A study of Mus musculus with 4 samples.

How the data were processed

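RNA was measured in 4 libraries of AML12 mouse hepatocytes, 2 with a control hairpin and 2 with a hairpin against Safb, delivered by lentivirus per the labels' protocols. The libraries were strand-specific and made from total RNA depleted of ribosomal RNA, per the labels' protocols. HISAT2, HTSeq, StringTie and DESeq2 were used with the mm10 genome, per the submitters' processing notes, which give no versions, order or annotation release. The values are the authors' deposited TPM, 1 per gene and library, and whether strand was used in counting is not given in the sources used here. Per the labels, a library's group and replicate number come from its title. All 4 libraries came from cells kept with 0.1 uM dexamethasone, a glucocorticoid, and 10% serum, per the labels.

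The deposited table holds 52200 rows with 52192 distinct gene identifiers. The 6 identifiers on more than 1 row were summed. Symbols had been turned into dates in 27 rows, so names, coordinates and gene types were taken by identifier from GENCODE mouse release 21 on GRCm38 (mm10), which holds 52045 of the identifiers and lacks 147. The TPM summed to 999891 in each shCtrl library and 999843 in each shSafb library. TPM keeps no counts, so the depth is unknown and no counting interval is given.

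Genes with a mean TPM of at least 1 over the 4 libraries were tested (13111). Each library was divided by the median, over tested genes above 0 in all libraries, of its ratio to the geometric mean, with factors of 1.031, 0.991, 0.992 and 0.995 for shCtrl 1, shCtrl 2, shSafb 1 and shSafb 2. log2(scaled TPM + 1) was fitted with limma (group only; empirical Bayes with an intensity trend; 2 residual and 2.61 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Printed means and SDs are of the deposited TPM over 2 libraries, and log2 changes are shSafb minus shCtrl with standard errors from limma. An exact permutation of 2 against 2 libraries could not reach 0.05 and was not used.

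Gene lists with at least 5 tested members were tested with camera against all other tested genes, with a preset inter-gene correlation of 0.01, and again with an estimated one. The groups, the filter, the test, the 33 lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Safb, Safb2 and Sltm; the 12 largest rises and 12 largest falls among called genes with a mean TPM of at least 2 and groups that do not overlap, leaving out predicted, clone-named, small RNA and pseudogene entries; up to 5 members with the smallest p of each list that passed or had at least 3 calls; and up to 2 of each other list. Identifiers starting with AC, AL, CT or CR and a number were also read as clone names, a detail added after the data were seen. Of the genes named with values, only those that a text marks as chosen after their values were seen lie outside the rule, and some genes that the rule selects are not reported here.

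The gene and list tests were tested on simulated data made from the real means and spreads, in 20 draws of 12747 to 12789 genes for the shSafb against shCtrl comparison, each with 200 genes changed. At a fold of 1.5, 29.6% of changed genes were called on average (18.5% to 45.5% over draws), at a fold of 2, 59.9% (47.6% to 74.2%), and at a fold of 4, 84.9% (71.9% to 93.2%). False calls made up 3.74% of calls on average (0.943% to 7.07%). Of 200 lists of 30 genes moved by 0.5 on the log2 scale, camera called 200 with the preset and 196 with an estimated correlation, and of 200 lists left in place it called 1 and 0. The simulated genes varied independently, which real list members need not do. Only 200 genes changed per draw, against 5805 called of 13111 in the data. A call therefore needed a lower unadjusted p in the draws, so the recovery and false call rates do not describe the data.

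Alternatives covered the pseudocount, the filter on low TPM, the scaling, the variance model, a replicate block, leaving out each library, a fold threshold and an estimated correlation. Removal of a loess trend on GC content and exonic length was added after seeing the data and used the 99.85% of tested genes with both values. Nuclear copies of mitochondrial genes were matched with BLAST 2.17.0. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.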

Results

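RNA was sequenced from AML12 cells, a mouse hepatocyte line, that carried either a control short hairpin RNA (shCtrl) or a hairpin against Safb (shSafb). Safb encodes scaffold attachment factor B, a nuclear matrix protein that binds DNA and RNA. Each group had 2 libraries, and every gene had 1 value per library in TPM, a transcript abundance scaled by gene length and to a fixed library total. TPM keeps no read totals, so the sequencing depth is unknown. Between 12946 and 13117 genes reached 1 TPM in a library. The 10 most abundant genes held 30.8% to 32.5% of the TPM, and small RNA genes held 30.1% to 32.1%. Mitochondrially encoded genes held 0.845% and 0.703% of the TPM in the shCtrl libraries against 0.318% and 0.343% in the shSafb libraries. These shares leave out near-identical copies in the nuclear genome. Across genes, Spearman's rho was 0.990 between the shCtrl libraries, 0.989 between the shSafb libraries and 0.951 to 0.952 between libraries of different groups. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

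The comparison asked how gene expression differed between Safb knockdown and control cells. Safb itself was lower in both shSafb libraries, at 15.8 and 15.02 TPM against 23.8 and 23.3 TPM in the shCtrl libraries. Its mean fell from 23.6 ± 0.354 to 15.4 ± 0.544 TPM (SD, n = 2 each), 1.53-fold, with a log2 change of -0.56 ± 0.07 (SE; limma, Benjamini-Hochberg adjusted p = 0.00411). The gene (ENSMUSG00000071054) lies on chromosome 17 from 56584825 to 56606294 on the plus strand of mm10. Its paralog Safb2, the next gene on that chromosome (56560965 to 56584585, minus strand), rose from 26.7 ± 0.538 to 34.2 ± 4.56 TPM, with a log2 change of 0.36 ± 0.10 (limma adjusted p = 0.0435). That call was lost without shCtrl replicate 1 (adjusted p = 0.131), without shCtrl replicate 2 (0.120) and without shSafb replicate 2 (0.113), and under 5 other settings (0.0244 to 0.131 over 15 alternatives). Sltm, which encodes the related SAFB-like transcription modulator, rose from 18.8 ± 0.992 to 24.1 ± 1.01 TPM, a log2 change of 0.37 ± 0.07 (limma adjusted p = 0.0139), a call lost without shCtrl replicate 2 (adjusted p = 0.0550) or shSafb replicate 1 (0.0730; 0.0119 to 0.0730 over all alternatives). Safb and Safb2 are similar in sequence, so reads could be split between them and both values are uncertain to that extent.

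Of the tested members of lists, 40 of 49 S phase and mitosis genes, 61 of 66 replication-dependent histones and 17 of 25 cholesterol synthesis and uptake genes were higher in the shSafb libraries, with 2, 0 and 3 lower. Of the mitochondrially encoded RNAs 20 of 30 were lower and 0 higher, of the fatty acid oxidation and ketone synthesis genes 11 of 22 lower and 3 higher, and of the major urinary protein and Cyp2 family genes 7 of 8 lower, while Cyp2s1 was 4.11-fold higher. In camera's list test, all 6 passed only with a preset inter-gene correlation. With an estimated one the camera adjusted p was 0.271, or 0.445 for fatty acid oxidation. Among liver genes the changes went both ways: Ass1, Afp and Trf rose and Alb fell. Of 13111 genes tested, 2867 were higher and 2938 lower in shSafb (limma, adjusted p under 0.05), which is 44.3% of the tested genes. The median size of the called changes was 0.56 on the log2 scale. With a fold of at least 1.5 also required, 1303 genes were higher and 1408 lower. Safb was just short of that cut (0.585 on the log2 scale) at -0.560. It was past it at -0.587 with a pseudocount of 0.1, -0.596 without shSafb replicate 1 and -0.600 with small RNA and mitochondrial genes left out. The number of genes higher fell to 1768 without shSafb replicate 1 and to 1764 without shSafb replicate 2. In 74.7% of the tested genes both values of one group lay outside those of the other, where chance alone gives 33.3%.

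**Figure D1:**
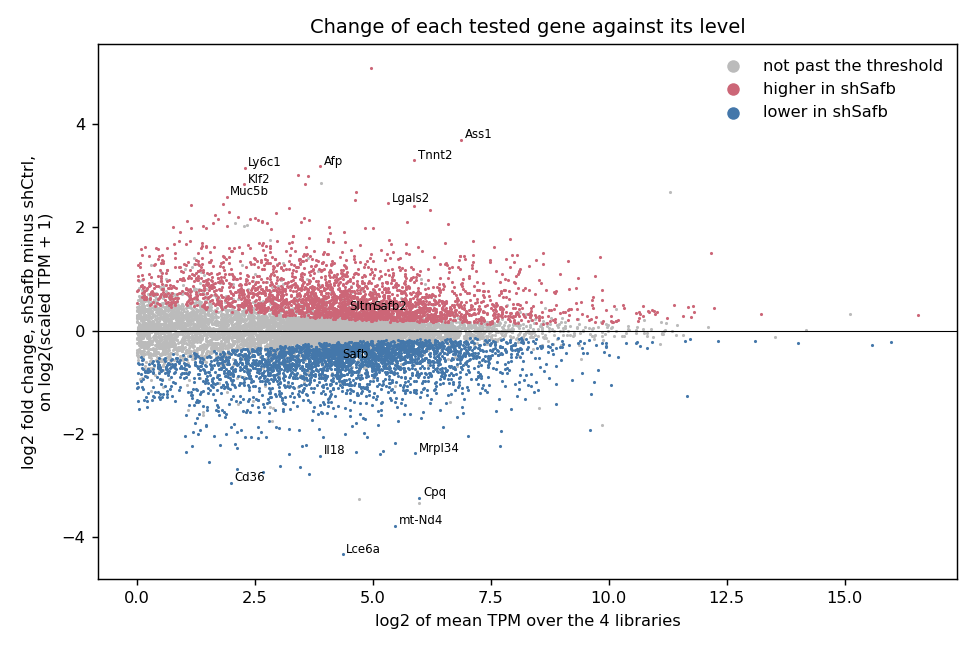
Each point is 1 tested gene, with the log2 of its mean TPM over the 4 libraries on the x axis and its log2 change, shSafb minus shCtrl, on log2(scaled TPM + 1) on the y axis. Red points mark the 2867 genes called higher, blue points the 2938 called lower and grey points the rest, and the labels name Safb, Safb2, Sltm and some of the genes with the largest called changes.

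Ass1, which encodes the urea cycle enzyme argininosuccinate synthetase, had the largest rise among the named genes on the log2(scaled TPM + 1) scale, from 16.2 ± 1.68 to 218 ± 0.6 TPM (13.4-fold; log2 change 3.70 ± 0.07, adjusted p = 4.01e-04). The gene (ENSMUSG00000076441) lies on chromosome 2 from 31470207 to 31520672. Tnnt2, encoding cardiac troponin T, rose from 10.2 ± 1.04 to 107 ± 4.13 TPM. Afp, encoding the fetal serum protein alpha-fetoprotein, rose from 2.17 ± 0.122 to 27.3 ± 0.555 TPM. Nts, the neurotensin gene, reached 19.7 ± 0.277 TPM from 1.62 ± 0.618 TPM, and Edn1, the endothelin-1 gene, reached 21.4 ± 0.107 TPM from 2.20 ± 0.56 TPM. Ly6c1 and Muc5b, a mucin gene, were under 1 TPM in both shCtrl libraries and averaged 9.55 ± 2.86 and 7.11 ± 0.326 TPM in shSafb. By the ratio of mean TPM, Klf2 (20.6-fold) and Muc5b (19.7-fold) rose more than Ass1, but both were under 1 TPM in shCtrl, so these folds are imprecise. Ly6c1, at 0 and 0.360 TPM in the shCtrl libraries, has no stable fold. Fxyd2 rose by 2.99 ± 0.22, Akr1b7 by 2.53 ± 0.08 and Lgals2 by 2.46 ± 0.07 on the log2 scale. Lgals2 overlaps Cdc42ep1 on the opposite strand, so its value is uncertain where the counting ignored strand.

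The largest fall among the named genes on the same scale was that of Lce6a, a late cornified envelope gene on chromosome 3 (92620081 to 92621660), from 40.1 ± 0.903 to 1.02 ± 0.116 TPM (log2 change -4.33 ± 0.09, adjusted p = 5.31e-04). Cpq, which encodes the secreted carboxypeptidase Q, fell from 116 ± 0.295 to 11.1 ± 0.151 TPM, 10.4-fold. Cd36, encoding a fatty acid uptake receptor, fell from 7.84 ± 0.175 to 0.14 ± 0.00729 TPM, 56.1-fold against 39.4-fold for Lce6a. Il18, an interleukin gene, fell from 25.5 ± 0.545 to 3.90 ± 0.745 TPM. Fbp2, encoding a fructose-bisphosphatase, fell from 16.4 ± 0.249 to 2.29 ± 0.157 TPM. The cytochrome P450 gene Cyp4f14 changed by -2.72 ± 0.12 on the log2 scale, Upk3b by -2.68 ± 0.16, Serpinb9b by -2.38 ± 0.07 and Mrpl34, a mitochondrial ribosomal protein gene, by -2.37 ± 0.15. S100b changed by -2.64 ± 0.11 and overlaps Dip2a on the opposite strand. Log2 changes are on the log2(scaled TPM + 1) scale and understate the change of genes near 0, such as Cd36, Ly6c1 and Muc5b.

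**Figure D2:**
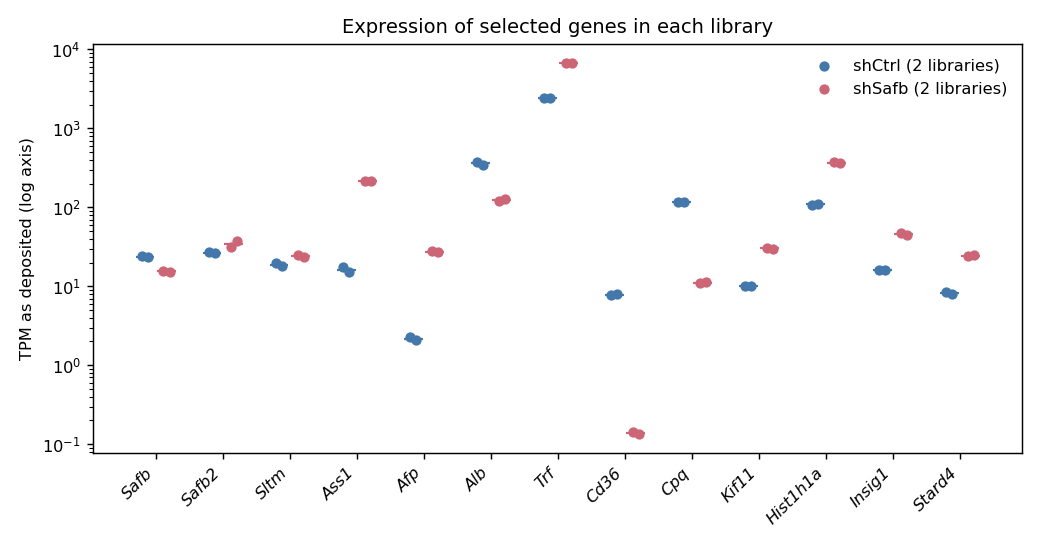
TPM of 13 genes in each of the 4 libraries on a log axis, with shCtrl in blue, shSafb in red and a short line at each group mean. Ass1 goes from 16.2 to 218 TPM and Cd36 from 7.84 to 0.14 TPM, while the means of Safb are 23.6 and 15.4 TPM.

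Of 33 gene lists fixed before the data were examined, 28 had at least 5 tested members, and 15 of these passed camera's test against all other genes with a preset inter-gene correlation of 0.01 (11 higher, 4 lower). With the correlation estimated per list, 0 lists passed, and the lowest adjusted p was 0.271. Several lists share that value through the Benjamini-Hochberg adjustment. Their unadjusted camera p ran from 0.0159 for S phase and mitosis genes to 0.116 for p53 targets. The correlations were estimated with 2 residual degrees of freedom and are imprecise, so a list that did not pass in this way is not shown to be unchanged. All 15 of camera's list calls therefore rest on the preset correlation. Limma's fry test was also planned, which asks whether a list's members moved on balance 1 way, without comparing them to other genes. The fry adjusted p was 0.00106 for the S phase and mitosis list and 0.00358 for the histones. It was 0.0581 for cytosolic ribosomal proteins, the only list called by camera that was not under 0.05 in fry. Type I interferon genes (fry adjusted p = 0.00778), glycolysis and hypoxia genes (0.00447) and glucocorticoid receptor targets (0.00926) were under 0.05 in fry, while camera did not call them.

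**Figure D3:**
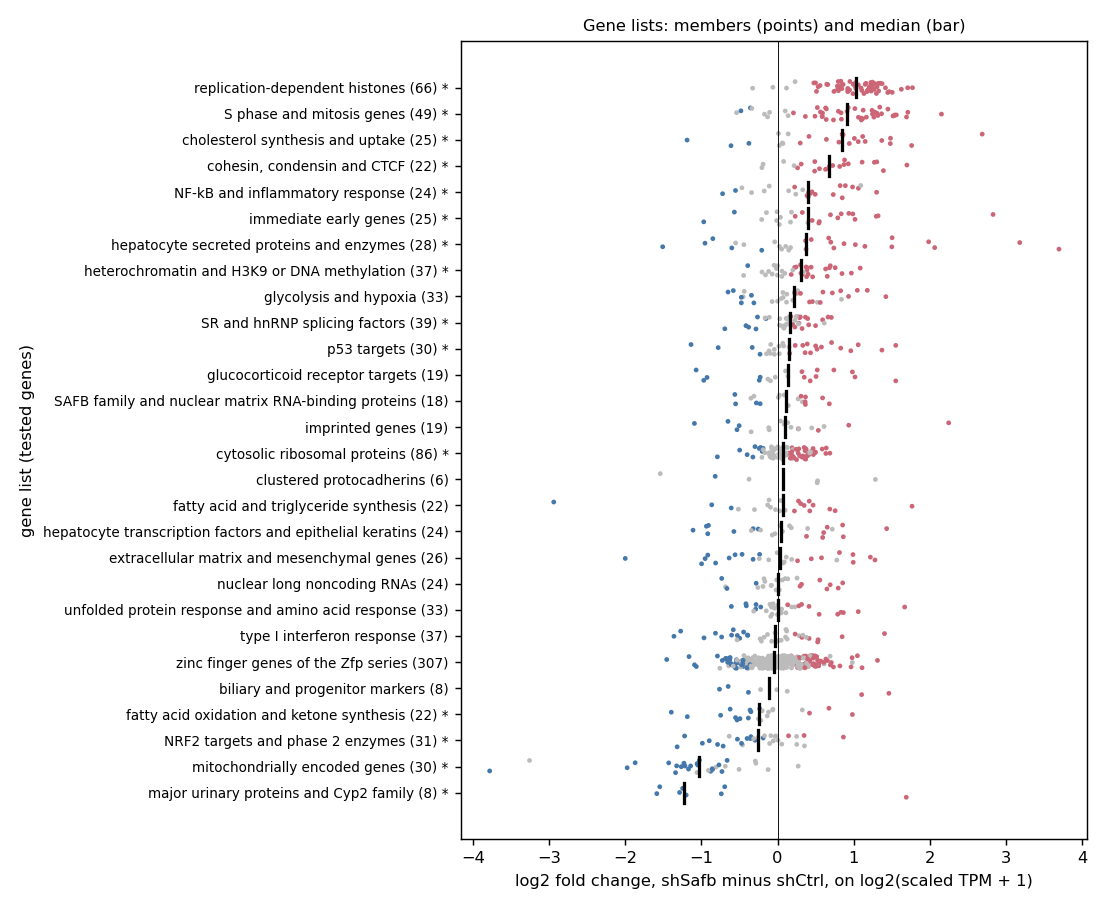
Log2 change, shSafb minus shCtrl, of every tested member (points) of the 28 tested lists, with the list median as a bar and the number of tested members in parentheses. Red points were called higher, blue lower and grey neither, and an asterisk marks the 15 lists with a camera adjusted p under 0.05 at the preset correlation. The medians run from -1.22 for the major urinary protein and Cyp2 list to 1.03 for the histones.

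Of 49 tested S phase and mitosis genes, 40 were higher, 2 lower and 7 not past the threshold, the same counts when adjusted over the list alone, with a median log2 change of 0.92 (camera adjusted p = 1.66e-10; adjusted p = 0.271 with an estimated correlation). Kif11, a mitotic spindle motor gene, rose from 10.1 ± 0.132 to 30.5 ± 0.633 TPM. Bub1b, a spindle checkpoint gene, rose from 10.1 ± 0.269 to 26.2 ± 1.097 TPM and Ccnb2, encoding cyclin B2, from 19.3 ± 1.046 to 41.8 ± 1.49995 TPM. Replication-dependent histone genes were higher in 61 of 66 cases and lower in 0, both over all genes and adjusted over the list alone (median 1.03, camera adjusted p = 5.77e-21; adjusted p = 0.271 with an estimated correlation). The linker histone gene Hist1h1a rose from 109 ± 3.87 to 368 ± 8.19 TPM and Hist1h2bk from 93.6 ± 0.204 to 286 ± 1.77 TPM. Histone genes are near-identical in places, so reads may be divided among them and single members are uncertain.

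Genes of cohesin, condensin and CTCF were higher in 18 of 22 cases and lower in 0, or 19 higher and 2 lower when adjusted over the list alone (median 0.67, camera adjusted p = 5.3e-06; adjusted p = 0.271 with an estimated correlation). Ncapg2, a condensin subunit gene, rose from 3.95 ± 0.302 to 14.8 ± 1.43 TPM and Smc4, a condensin core subunit gene, from 9.82 ± 0.29 to 24.7 ± 0.277 TPM. Wapl, encoding a cohesin release factor, rose from 39.2 ± 1.32 to 64.2 ± 0.0876 TPM. Heterochromatin and H3K9 or DNA methylation genes were higher in 21 of 37 cases and lower in 1, or 21 and 2 when adjusted over the list alone (median 0.30, camera adjusted p = 0.00264; adjusted p = 0.271 with an estimated correlation). Lbr, the lamin B receptor gene, rose from 26.0 ± 0.895 to 55.3 ± 3.43 TPM. Hells, a chromatin remodeller gene, rose from 11.2 ± 0.584 to 22.4 ± 0.712 TPM and Cbx5, encoding the heterochromatin protein HP1 alpha, from 89.6 ± 5.43 to 122 ± 2.70 TPM.

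Cholesterol synthesis and uptake genes were higher in 17 of 25 cases and lower in 3, the same when adjusted over the list alone (median 0.85, camera adjusted p = 4.94e-05; adjusted p = 0.271 with an estimated correlation). Insig1, encoding a sterol-responsive protein of the endoplasmic reticulum, rose from 16.1 ± 0.0381 to 46.2 ± 1.61 TPM, and Stard4, encoding a sterol transport protein, from 8.23 ± 0.333 to 24.3 ± 0.372 TPM. Fatty acid oxidation and ketone synthesis genes were lower in 11 of 22 cases and higher in 3, or 12 lower and 3 higher when adjusted over the list alone (median -0.24, camera adjusted p = 0.0208; adjusted p = 0.445 with an estimated correlation). Acadm, encoding medium-chain acyl-CoA dehydrogenase, fell from 91.0 ± 2.39 to 38.8 ± 0.662 TPM and Hadh, encoding a hydroxyacyl-CoA dehydrogenase, from 137 ± 2.56 to 91.4 ± 0.218 TPM, while Pdk4, a pyruvate dehydrogenase kinase gene, rose from 7.36 ± 0.313 to 15.3 ± 0.376 TPM. Fatty acid and triglyceride synthesis genes did not pass as a list, with 10 of 22 higher and 3 lower, the same adjusted over the list alone (median 0.07, camera adjusted p = 0.405). Scd1, a stearoyl-CoA desaturase gene, rose from 7.07 ± 0.193 to 26.0 ± 0.385 TPM and the fatty acid elongase gene Elovl5 fell from 97.9 ± 3.66 to 52.4 ± 0.174 TPM. Glycolysis and hypoxia genes did not pass as a list, with 12 of 33 higher and 6 lower, or 14 and 7 adjusted over the list alone (median 0.22, camera adjusted p = 0.0987), and the glycolytic enzyme gene Pgam1 rose from 263 ± 1.11 to 426 ± 6.89 TPM. Pfkm, a phosphofructokinase gene that overlaps Senp1 on the opposite strand, fell from 42.7 ± 0.543 to 26.4 ± 0.685 TPM.

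Hepatocyte secreted proteins and enzymes were higher in 15 of 28 cases and lower in 5, or 15 and 6 when adjusted over the list alone (median 0.37, camera adjusted p = 0.0208; adjusted p = 0.556 with an estimated correlation). The call was lost when genes with a mean TPM of at least 0.1 were tested (median 0.07, adjusted p = 0.356) or with no filter (median 0.02, adjusted p = 0.644), and over 16 alternatives at the preset correlation the adjusted p ran from 0.0103 to 0.644. Trf, the transferrin gene, rose from 2435 ± 24.6 to 6796 ± 26.1 TPM, and overlaps the predicted gene Gm20425. Hp, the haptoglobin gene, rose from 37.2 ± 2.06 to 156 ± 3.29 TPM, and Alb, the albumin gene, fell from 362 ± 22.7 to 124 ± 3.52 TPM. Major urinary protein and Cyp2 family genes were lower in 7 of 8 cases and higher in 1, the same adjusted over the list alone (median -1.22, camera adjusted p = 0.00403; adjusted p = 0.271 with an estimated correlation). The named members were all Cyp2 genes: Cyp2j5 fell from 20.3 ± 0.565 to 6.19 ± 0.289 TPM, Cyp2d22 from 23.2 ± 1.26 to 6.96 ± 1.14 TPM, and Cyp2s1 rose from 2.37 ± 0.207 to 9.73 ± 0.615 TPM. Members of the Cyp2 family resemble each other, so reads could be shared. Hepatocyte transcription factors and epithelial keratins went both ways, with 7 of 24 higher and 7 lower, or 10 and 7 adjusted over the list alone (median 0.05, camera adjusted p = 0.776). Foxa3, a liver forkhead factor gene, rose from 42.7 ± 2.01 to 115 ± 0.923 TPM and Cdh1, the E-cadherin gene, fell from 164 ± 13.4 to 73.8 ± 0.54 TPM.

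NF-kB and inflammatory genes were higher in 14 of 24 cases and lower in 2, the same adjusted over the list alone (median 0.41, camera adjusted p = 0.00816; adjusted p = 0.271 with an estimated correlation). The complement gene C3 rose from 552 ± 24.9 to 1133 ± 3.90 TPM, the chemokine gene Ccl2 from 460 ± 4.33 to 800.5 ± 13.7 TPM and the adhesion molecule gene Icam1 from 48.7 ± 0.653 to 95.7 ± 2.42 TPM. Immediate early genes were higher in 14 of 25 cases and lower in 2, or 15 and 4 adjusted over the list alone (median 0.40, camera adjusted p = 0.00264; adjusted p = 0.271 with an estimated correlation). Klf2, a zinc finger transcription factor gene, rose from 0.446 ± 0.0671 to 9.20 ± 0.00633 TPM and Klf6, another of this family, from 158 ± 6.79 to 308 ± 1.23 TPM. Targets of p53 were higher in 15 of 30 cases and lower in 4, the same adjusted over the list alone (median 0.16, camera adjusted p = 0.0377; adjusted p = 0.271 with an estimated correlation), a call lost without shCtrl replicate 2 (adjusted p = 0.0647), without shSafb replicate 2 (0.0775) and with genes from a mean TPM of 0.1 tested (0.0566; 0.0227 to 0.0775 over the alternatives at the preset correlation). Perp, a desmosome gene, rose from 199 ± 2.28 to 506 ± 6.56 TPM, Ddit4, encoding an inhibitor of mTORC1, from 33.5 ± 1.91 to 98.6 ± 1.91 TPM, and Gdf15, a stress-induced cytokine gene, fell from 97.8 ± 2.46 to 43.2 ± 3.30 TPM.

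NRF2 targets and phase 2 enzymes were lower in 13 of 31 cases and higher in 3, the same adjusted over the list alone (median -0.26, camera adjusted p = 0.0377; adjusted p = 0.271 with an estimated correlation), a call lost without shCtrl replicate 2 (adjusted p = 0.0581) and with the GC and length trend removed (0.0922; 0.00406 to 0.0922 over the alternatives at the preset correlation). Ephx1, the microsomal epoxide hydrolase gene, fell from 430.4 ± 15.5 to 169 ± 6.16 TPM and Srxn1, the sulfiredoxin gene, from 21.2 ± 1.64 to 10.7 ± 0.678 TPM. Type I interferon response genes did not pass as a list, with 7 of 37 higher and 12 lower, the same adjusted over the list alone (median -0.03, camera adjusted p = 0.405). Irf1, an interferon regulatory factor gene, fell from 89.7 ± 1.01 to 44.7 ± 1.65 TPM, and Usp18, which overlaps Gm44148 on the opposite strand, rose from 2.67 ± 0.279 to 8.56 ± 0.119 TPM. Unfolded protein and amino acid response genes were higher in 10 of 33 cases and lower in 6, the same adjusted over the list alone (median 0.00, camera adjusted p = 0.649), with Atf3, a stress-response transcription factor gene, up from 113 ± 5.29 to 192 ± 3.61 TPM and Creld2, an endoplasmic reticulum protein gene, down from 45.8 ± 0.285 to 29.2 ± 1.68 TPM. Glucocorticoid receptor targets were higher in 9 of 19 cases and lower in 5, the same adjusted over the list alone (median 0.14, camera adjusted p = 0.405). Ddit4 and Pdk4, given above, are among those that rose, while Mt2, a metallothionein gene, fell from 127 ± 12.4 to 65.2 ± 1.09 TPM.

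Mitochondrially encoded genes were lower in 20 of 30 cases and higher in 0, or 22 lower when adjusted over the list alone (median -1.04, camera adjusted p = 3.57e-07; adjusted p = 0.271 with an estimated correlation). The cytochrome oxidase gene mt-Co3 fell from 231 ± 8.88 to 102 ± 1.89 TPM, 2.26-fold. The complex I gene mt-Nd6 fell from 97.9 ± 3.94 to 56.0 ± 0.398 TPM, and it overlaps mt-Nd5 on the opposite strand. Another complex I gene, mt-Nd4 (positions 10167 to 11544), fell 16.3-fold, from 83.5 ± 14.8 to 5.13 ± 1.77 TPM, a log2 change of -3.78 ± 0.23. Several of these genes share reads with near-identical nuclear copies on chromosome 1, so single members are uncertain. In 1 such case, chosen after its values were seen, mt-Co2 is listed at 47.0, 38.6, 19.197 and 0 TPM in shCtrl 1, shCtrl 2, shSafb 1 and shSafb 2 and was not called.

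SAFB family and nuclear matrix RNA-binding protein genes did not pass as a list, with 6 of 18 higher and 4 lower, or 8 and 4 adjusted over the list alone (median 0.11, camera adjusted p = 0.570). Lmnb1, the lamin B1 gene, rose from 21.5 ± 0.519 to 34.5 ± 0.838 TPM, while Lmnb2, the lamin B2 gene, fell from 23.7 ± 0.481 to 15.6 ± 0.00824 TPM. SR and hnRNP splicing factor genes were higher in 14 of 39 cases and lower in 6, the same adjusted over the list alone (median 0.16, camera adjusted p = 0.0377; adjusted p = 0.271 with an estimated correlation). That call was lost without shCtrl replicate 1 (adjusted p = 0.0755), without shSafb replicate 1 (0.0581), without shSafb replicate 2 (0.0600) and under 3 other settings (0.0277 to 0.145 over the alternatives at the preset correlation). Srsf10, an SR protein gene, rose from 22.9 ± 0.0807 to 37.4 ± 1.71 TPM and Hnrnpr, an hnRNP gene, fell from 45.4 ± 1.83 to 33.2 ± 1.204 TPM. Cytosolic ribosomal protein genes were higher in 32 of 86 cases and lower in 9, or 33 and 9 adjusted over the list alone (median 0.08, camera adjusted p = 0.0377; adjusted p = 0.690 with an estimated correlation). Under quantile normalization the adjusted p was 0.389 with a median of 0.03, with the replicate block it was 0.0559, without shCtrl replicate 1 it was 0.0906 and without shSafb replicate 1 it was 0.103. The call was also lost under 4 other settings (0.00564 to 0.389 over the alternatives at the preset correlation). Rpl8 rose from 2236 ± 9.74 to 3098 ± 66.8 TPM and Rps20 fell from 111 ± 1.90 to 62.6 ± 0.418 TPM, and both share sequence with processed pseudogenes.

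Nuclear long noncoding RNAs were higher in 7 of 24 cases and lower in 3, the same adjusted over the list alone (median 0.006, camera adjusted p = 0.666). Neat1, the scaffold of paraspeckles, rose from 18.4 ± 1.28 to 32.2 ± 0.763 TPM, and overlaps the predicted gene Gm27505, while 2900097C17Rik fell from 96.3 ± 2.08 to 59.3 ± 0.533 TPM. Zinc finger genes of the Zfp series were higher in 47 of 307 cases and lower in 36, or 35 and 27 adjusted over the list alone (median -0.05, camera adjusted p = 0.776). Zfp568 rose from 28.7 ± 0.976 to 56.6 ± 0.445 TPM and Zfp707 fell from 24.9 ± 0.699 to 8.31 ± 1.09 TPM. Imprinted genes were higher in 4 of 19 cases and lower in 4, the same adjusted over the list alone (median 0.10, camera adjusted p = 0.776). H19, an imprinted noncoding RNA, rose from 0.466 ± 0.36 to 5.81 ± 0.056 TPM and Slc22a18 fell from 39.9 ± 3.64 to 17.8 ± 0.299 TPM. Clustered protocadherins had 6 tested members, 0 higher and 1 lower, the same adjusted over the list alone (median 0.07, mean -0.07, camera direction down, adjusted p = 0.782). The call on Pcdhgb4 (log2 change -0.82 ± 0.18) was lost without shCtrl replicate 1 (adjusted p = 0.0655), shCtrl replicate 2 (0.109) or shSafb replicate 2 (0.0817; 0.0163 to 0.109 over 14 alternatives). Pcdhgb8 averaged 4.17 ± 5.83 TPM in shCtrl and was not called, with an adjusted p of 0.00802 without shCtrl replicate 1 (0.00802 to 0.914 over the alternatives), and both genes share exons with neighbours in their cluster.

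Extracellular matrix and mesenchymal genes did not pass as a list, with 8 of 26 higher and 10 lower, or 9 and 11 adjusted over the list alone (median 0.03, mean -0.02, camera direction down, adjusted p = 0.831). Thbs1, the thrombospondin 1 gene, rose from 12.7 ± 0.355 to 30.3 ± 0.105 TPM and Vim, the vimentin gene, fell from 564 ± 27.2 to 293 ± 2.96 TPM. Biliary and progenitor markers were higher in 2 of 8 cases and lower in 3, the same adjusted over the list alone (median -0.12, mean 0.08, camera direction down, adjusted p = 0.831). Krt19, a bile duct keratin gene, rose from 320 ± 0.13 to 677 ± 2.19 TPM and Spp1, the osteopontin gene, fell from 1105 ± 5.03 to 640.1 ± 43.0 TPM. The lower calls on Sox9 (log2 change -0.38) and Cftr (-0.65) were lost without shCtrl replicate 1 (log2 change -0.27 and -0.66). They were also lost without shSafb replicate 1 (-0.34 and -0.67) and without shSafb replicate 2 (-0.43 and -0.63). The call on Cftr was lost without shCtrl replicate 2 as well (-0.63), and that on Sox9 with no filter on low values (limma adjusted p = 0.0563). Over all alternatives the adjusted p ran from 0.0205 to 0.106 for Sox9 and from 0.00540 to 0.0912 for Cftr.

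Markers of fibroblasts and stellate cells, of macrophages and leukocytes and of endothelial cells were mostly under the filter. Of the fibroblast and stellate cell markers 2 were tested: Vtn, which hepatocytes also express, fell from 100 ± 3.83 to 32.6 ± 2.82 TPM, and Des was at 1.15 ± 0.0402 and 1.048 ± 0.0428 TPM. Of 3 tested macrophage and leukocyte markers, Csf1r rose from 0.345 ± 0.149 to 1.82 ± 0.139 TPM, overlapping Hmgxb3 on the opposite strand, and Cd14 fell from 117 ± 3.59 to 64.7 ± 1.24 TPM. The 1 tested endothelial marker, Egfl7, was at 13.9 ± 0.165 and 14.9 ± 0.796 TPM, not past the threshold, and overlaps Agpat2 on the opposite strand. Germline genes silenced by DNA methylation had 2 tested members, neither past the threshold: Tex14 at 1.55 ± 0.33 and 2.01 ± 0.579 TPM, and Zcwpw1 at 9.40 ± 2.30 and 9.44 ± 0.361 TPM. Of the olfactory and vomeronasal receptors 1 was tested, Olfr482, at 1.29 ± 0.203 and 1.06 ± 0.214 TPM, also not past the threshold.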

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

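Removing the GC and length trend was the only alternative chosen after the data were seen. The log2 change of Safb stayed between -0.60 and -0.49 and past the threshold under the alternatives that refit it, on both sides of a fold of 1.5. Of the other choices, requiring a fold of at least 1.5 gave 1303 genes higher and 1408 lower by its own construction, and estimating the inter-gene correlation left 0 of 15 lists past the threshold. Leaving out 1 library, where the lone library of a group is assumed to vary like the others, gave 1764 to 2193 genes higher, 1987 to 2156 lower and 13 lists, with 1 residual degree of freedom; the 1768 and 1764 genes higher without shSafb replicate 1 or 2 come from fewer samples. With the replicate block 5226 genes were called (2540 higher, 2686 lower) against 5805. Same-numbered libraries did not deviate together (correlation of deviations -0.06). That shows no shared shift, but with 2 libraries per group it cannot tell whether the numbers mark pairs. Of the 5805 calls, 5498 were kept with no scaling and 5655 under quantile normalization, where 2 of those not kept changed sign. Without small RNA and mitochondrial genes, 5549 of the 5705 calls still tested were kept. In these 3 settings 46.4%, 49.99% and 45.5% of calls were higher against 49.4%, and the median of all genes shifted by at most 0.03. For named genes and lists, the direction changed only where the threshold was not passed, and the cause was not tested: the extracellular matrix list changed its camera direction with a mean TPM of at least 0.1 (median 0.0407), no filter (0.0405), a mean TPM of at least 5 (0.0444) and small RNA and mitochondrial genes left out (0.0447), and also without shCtrl replicate 1 (-0.0243; -0.0497 to 0.0694 over the libraries left out); the biliary list with no filter (-0.00647) and a mean TPM of at least 5 (0.00119); the Zfp list with a mean TPM of at least 5 (-0.0369); the protocadherin list without shCtrl replicate 1 (0.675; -0.412 to 0.675); the nuclear noncoding RNA list with the GC and length trend removed (-0.0459); and Zcwpw1 (-0.155; -0.155 to 0.247) and Pcdhgb8 (0.0404; -3.12 to 0.0404) without shCtrl replicate 2. Among single genes, 2370 results kept direction and side of the threshold, 21 lost the call, 1 gained it and 2 changed sign; among lists these were 426, 36, 2 and 10. Glycolysis and hypoxia passed with a mean TPM of at least 5 (adjusted p = 0.0443) and with the GC and length trend removed (0.0499). With depth unknown, the precision of genes near 1 TPM cannot be stated.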

Other observations

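The genes and lists of the first paragraph and the gene classes of the next were chosen after their values were seen, as were the tests below on GC and length of the S phase list, the shortest genes, cycling cells, scaling, nuclear-encoded subunits, the nuclear copies of mitochondrial genes, whole chromosomes, neighbouring genes, small RNA genes, replicates and YAP and TAZ targets. Ctnna1, which encodes the adherens junction protein alpha-catenin, fell 4.80-fold, from 341 ± 10.6 to 71.1 ± 1.21 TPM (log2 change -2.22 ± 0.04), and ranked 4 by p among the 13111 genes tested, where Safb ranked 1788. Crk, encoding a signalling adaptor protein, rose from 19.4 ± 0.41 to 86.0 ± 2.78 TPM. The major hepatocyte RNAs Ttr (2280 ± 45.2 and 2183 ± 8.28 TPM) and Krt8 (2300 ± 45.8 and 2153 ± 48.0 TPM) did not pass the threshold. Scarna10 is listed at 123 TPM in shCtrl 1 and 2696 TPM in shCtrl 2. Nuclear-encoded respiratory chain subunits were higher in 38 of 78 cases and lower in 9 (median 0.19), mitochondrial ribosomal protein genes higher in 16 of 79 and lower in 11 (median 0.07), and YAP and TAZ targets higher in 5 of 20 and lower in 6. If loss of alpha-catenin released YAP and TAZ, their targets should rise, but these went both ways around a median of -0.1126, which does not decide that hypothesis.

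Called genes of classes other than protein-coding genes went different ways. Among processed pseudogenes 88 were higher and 24 lower of 457 tested, and among genes of GENCODE's class still awaiting experimental evidence (TEC) 51 and 6 of 274, against 2550 and 2739 of 11235 protein-coding genes (Fisher's exact test, two-sided, over the classes with enough calls, adjusted p = 7.42e-10 for each). Small nucleolar RNA genes were higher in 21 cases and lower in 4 of 168 (adjusted p = 0.0022), small nuclear RNA genes in 13 and 2 of 57 (0.0137) and sense intronic RNA genes in 11 and 2 of 51 (0.0298). Mitochondrial tRNA genes were lower in 8 of 16 cases and higher in 0 (adjusted p = 0.0274). Antisense RNA genes, with 13 higher and 28 lower of 156 (adjusted p = 0.0993), and bidirectional promoter RNA genes, with 3 and 9 of 41 (0.281), were not past the threshold, and long intergenic RNA genes went both ways, with 50 higher and 40 lower of 204 (adjusted p = 0.287). Processed pseudogenes share reads with their parent genes, so their counts are uncertain, and genes are not independent replicates. Small nucleolar RNA genes such as Snord80, which overlaps Gas5 on the same strand, can hold reads of the gene around them. The same holds for sense intronic RNA genes, so the counts of both classes are also uncertain.

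Of the S phase and mitosis genes 40 of 49 and of the histone genes 61 of 66 were higher in shSafb. Neither list passed camera with an estimated inter-gene correlation, where both share an adjusted p of 0.271 (0.0159 and 0.0842 unadjusted). With the trend on GC and length removed the S phase and mitosis median was 0.9523, which argues against such a trend as the whole cause. The 1948 non-histone genes in the range of length (381 to 2586 nt) and GC of most histones had a median of -0.04447. Of these, 402 were higher and 528 lower. That range reaches far beyond the median histone gene (532 nt), so this set says little about short transcripts. The 37 non-histone genes no longer than 532 nt had a median of -0.19 (5 higher, 10 lower). Their quartiles were -0.69 and 0.18, against a median of 1.03 for the histones. These 37 genes argue against short length alone as the whole cause. Small nucleolar and small nuclear RNA genes moved the same way as the histones but by less, with medians of 0.15 and 0.24. A bias that these classes share with the histones was not tested and stays open. Both G1/S genes (14 of 23 higher, 2 lower, median 0.5232) and G2 and mitosis genes (26 of 26 higher, median 1.27) had medians above 0, but these are the same 49 genes, so this restates the pattern. A higher share of cycling cells in shSafb stays open, and cell numbers were not analysed here.

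Of 30 mitochondrially encoded RNAs 20 were lower, 0 higher and 10 not past the threshold, and the list did not pass with an estimated correlation (adjusted p = 0.271). The list's median was -1.038 or lower under the scalings that keep these genes. The main scaling factors ran only from 0.991 to 1.031, so this comparison could hardly have come out otherwise. Factors so close to 1 are too small to account for such a median, which argues against scaling of whole libraries. The median of 0.1941 for nuclear-encoded respiratory subunits argues against a joint fall of both sets. For mt-Nd4, the length-weighted sum with its chromosome 1 copy Gm28439 (24611535 to 24612410) changed by -3.048 on the log2 scale, so reads moving to that copy are unlikely to be the cause of its larger fall. That copy was 1.795-fold lower and those of mt-Nd3, mt-Co1, mt-Co2, mt-Co3 and mt-Atp6 in this stretch 1.796 to 2.33-fold lower, while the mt-Nd4l copy Gm10222 is at 9.95 and 0.264 TPM in the shCtrl libraries and 0.201 and 0.184 TPM in the shSafb libraries. What lowers these RNAs, in the cells or in the preparation of the libraries, stays open, and no biological explanation other than the joint fall was tested.

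Of the tested genes 44.3% were called while Safb fell 1.53-fold, and 2874 called genes changed by more than Safb. The chromosome median farthest from 0 was -0.08438 (chromosome 6), which argues against gained or lost chromosomes. Without small RNA and mitochondrial genes 6025 genes were called, but the main scaling already removes a common shift, so this count decides little. Small RNA genes held 30.1% and 32.1% of the TPM in shCtrl against 30.9% and 31.4% in shSafb. Mitochondrial genes held at most 0.845%, not counting their nuclear copies. Such shares argue against these genes' part of the TPM as the cause. For segments, 1 of 213 runs of 50 neighbouring genes had a median beyond 0.3, as many as in 2 of 100 shuffles of gene order; that met what had been written beforehand as speaking for segments, but the run is the histone cluster on chromosome 13 (21513222 to 23747241; 45 histone genes), 0 runs passed without histones, and it held 0.834% of the called protein-coding genes. Without histones, fold changes of adjacent genes correlated by 0.0754 against at most 0.0266 in 100 shuffles (0.0909 and 0.0253 with them) and at 5 genes distance by 0.00546 against at most 0.0190, which with that share argues against long segments as the whole cause, a reading decided after the result was seen, and leaves small groups of neighbours open. Replicates that share a culture or RNA preparation, with a median difference of at most 0.11 within a group, cannot be told apart from closely matched separate cultures because the labels do not say which they were, and an effect of Safb knockdown itself stays open beside it. Each group carried its own hairpin. Other effects of a hairpin, or other differences between the cultures, therefore cannot be told apart from an effect of the knockdown.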
